A study of Mus musculus with 109 samples.

How the data were processed

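The series measured 4C-seq contacts of 12 baits with HindIII as first and DpnII as second enzyme in mouse C127 cells. The unit deposited by the authors was raw read counts per HindIII site, and per the submitters' processing notes BWA 0.5.9 and the mm9 build were used; read filters were not given in the sources used here. The deposited counts were used as they were. All positions of the table equalled the HindIII sites of mm9 on each of its 21 chromosomes. Baits were located by matching the labels' bar code to the supplied mm9 sequence, and genes were named from the GENCODE annotation of the same build. Coordinates are 1-based.

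Each column was checked for the bait within 100 kb of which most reads lay. The 39 columns of the chromosome 16 and 17 baits and of 1.5 h failed this check as a set (35 of 39) and were left out, so that designs planned for 12 baits were run on 6. No column was given another label. The 2 technical replicates labelled 2 h were summed and counted as 1 library, as planned before the data were examined, although they did not share sites beyond the level of other pairs. Libraries were labelled mitosis, 30 min, 1, 2, 3 and 4 h after mitosis, G2 and G0, and grouped as first hour (30 min and 1 h, 4 libraries per bait) and 2 to 4 h (3 per bait). Labels call most replicates biological; where cultures were shared between baits, p-values measure the spread between baits and libraries only. Reads are PCR products without molecular identifiers, so read numbers give no counting interval for ligations and captured sites (1 read or more) were used beside reads.

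For regions, reads were summed per bait in 500-kb bins more than 2 Mb away and in 100-kb bins within 2 Mb, leaving out 50 kb on each side of the bait. Bins were kept by filterByExpr and tested with edgeR 4.0.16 (TMM, glmQLFit robust, glmQLFTest; R 4.3.3), all libraries of a bait in 1 fit. Benjamini-Hochberg adjustment ran over the bins of all baits together, at 0.05. DESeq2 1.42.0 was an alternative. The standard error of a log2 fold change was taken from the quasi-likelihood F. Named regions were, by a rule fixed before the data were examined, the 10 largest rises and falls past the threshold with no overlap between labels (5 for near-bait bins), at most 3 of each per bait and 2 Mb apart; exceptions are named in the text. One region among the highest of the mean profiles is not reported here. CPM values were computed from the counts of tested bins only.

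Shares were computed on reads more than 20 kb from the bait. Profiles were log2 observed over expected captured sites per bin, with the expected share from a lowess on log distance (span 0.5, pseudocount 0.5), in libraries of a bait thinned to the same number of captured sites (682 to 2921), averaged over 10 draws. Bait-to-bait contacts used 1-Mb windows. Baits, or pairs of baits, were the units of two-sided sign-flip permutation tests, all enumerated; pairs share baits and were treated as independent. Correlations used 100000 permutations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and pandas 2.3.3 was used.

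Both scripts were tested on simulated data. With 200 of 1462 bins changed, 3.94% of 127 calls were false and 0 had the wrong sign. Simulated profiles of 243 bins at 1469 captured sites had a mean r of 0.496 with libraries of the same pattern and -0.00840 with those of another. Captured sites beyond 2 Mb ran from 687 to 22931 per library, the fewest in libraries labelled 3 h and 4 h, which limits their profiles. Alternatives were other bin sizes and distances, no filter, captured sites, capped reads, a replicate block, each replicate left out, and, added after the labels were checked, fits without the libraries or baits in doubt and, later, scaling by read totals and shares without 1 far site of B44.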

Results

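Circular chromosome conformation capture with sequencing (4C-seq) reads which HindIII sites of the genome were ligated to 1 chosen fragment, the bait. It was run in mouse C127 cells, a line from a mammary tumour, at 12 baits and at labelled times from mitosis through early G1, in G2 and in serum-starved G0. The series asks when domain-scale and long-range contacts form after mitosis relative to the replication timing program. The deposited table held 109 libraries as read counts at 823352 HindIII sites. The 6 baits of chromosome 8 (mm9) are the ones compared below, in 70 libraries of 266006 to 8826711 reads (median 2985117). B7 (primer TATTAGGACAGACAGAAGCTT, chromosome 8, 7223950 to 7223970) lay between genes, 1393464 bp from Efnb2, with 0 protein-coding genes within 500 kb. B53 (AAACATGTTTGGCCAAGCTT, 52961959 to 52961978) was also intergenic, 1635102 bp from Aga, with 0 such genes. B44 (GGTCATCCCTTTAGAAGCTT, 44417335 to 44417354) was intergenic, 24972 bp from Zfp42, which encodes a zinc finger protein of pluripotent cells, with 8 genes nearby. B118 (CCTCATACAGCTGGAAGCTT, 118459309 to 118459328) was intergenic, 227615 bp from Maf, a leucine zipper transcription factor, with 1 gene nearby. B26 (TTGAGTTTGACGCCAAGCTT, 26774313 to 26774332) lay in an intron of Whsc1l1, a histone methyltransferase gene, with 19 genes nearby. B87 (GGGCGGAGATGGAAGCTT, 87434064 to 87434081) lay in an intron of Dnase2a, which encodes a lysosomal nuclease, with 38 genes nearby.

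The labels went against the data in 2 places, so each library is called by its label only. Of the 39 columns labelled as chromosome 16 baits, chromosome 17 baits or 1.5 h, 35 had their reads beside another bait than the label names, and all 39 were left out. The other 70 columns, all of chromosome 8, had their reads beside the labelled bait. At all 6 of these baits the library labelled 1 h replicate 2 and the library labelled 2 h technical replicate 1 shared 64.9% to 96.7% of the smaller library's captured sites on other chromosomes, 5.48 to 25.3 times the number chance gives. The libraries labelled as the 2 technical replicates of 2 h shared 8.57% to 27.0%, 1.90 to 2.61 times chance, and other pairs of a bait had medians of 1.73 to 2.81 times. Some other pairs shared far more than these medians. At B26, B44, B53 and B118 a library labelled G0 shared sites with 1 h replicate 2 and with 2 h technical replicate 1, as given in the last paragraph. Every direction drawn below from a labelled time therefore holds for the libraries so labelled, and not for the cell cycle phase the label names.

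**Figure D1:**
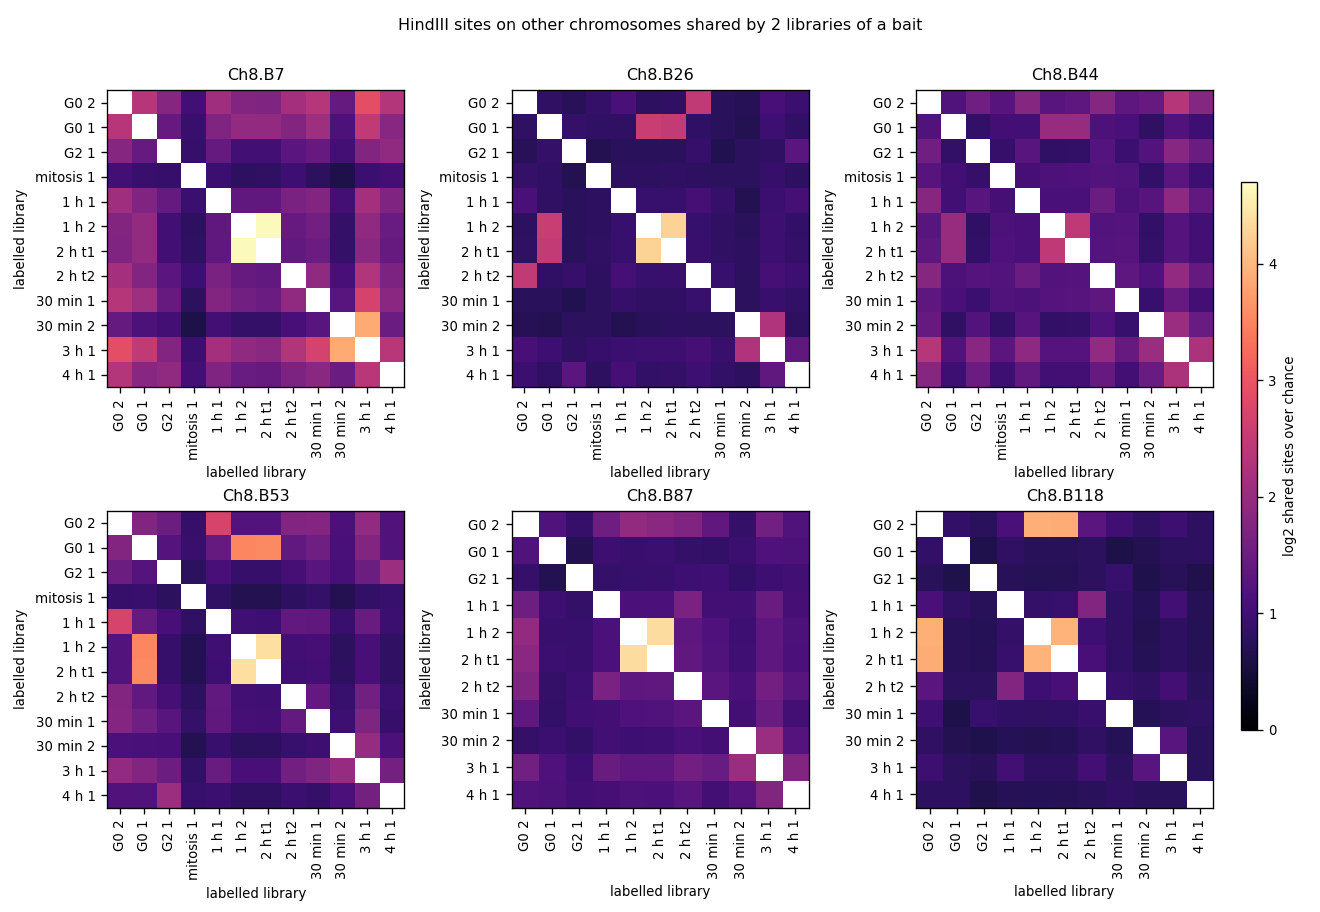
Each square gives, for 2 labelled libraries of 1 chromosome 8 bait (rows and columns, in the order of the table), the log2 ratio of shared HindIII sites on other chromosomes to the number chance gives; t marks a technical replicate. The brightest square of each bait is that of the libraries labelled 1 h replicate 2 and 2 h technical replicate 1, at 5.48 to 25.3 times chance.

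In profiles averaged over the libraries of a bait, the GC-rich baits B26, B87 and B118 met GC-rich and gene-rich parts of chromosome 8, and the GC-poor baits B7 and B53 met gene-poor parts. At the Dnase2a bait (49.9% GC in its 500-kb bin, 20 protein-coding genes), the mean contact profile over 10 libraries rose with GC content across 243 bins (Spearman rho 0.795) and with the number of genes (0.595). The Whsc1l1 bait (45.0% GC, 12 genes) gave rho values of 0.603 and 0.582, and the bait near Maf (43.9% GC, 1 gene) gave 0.550 and 0.427. The signs were opposite at B53 (36.2% GC, 0 genes), with -0.399 for GC and -0.527 for genes. B7 (37.1% GC, 0 genes) gave -0.124 and -0.347, and the Zfp42-side bait B44 (40.5% GC, 4 genes) gave 0.0614 and -0.111. The 25 bins most enriched with the Dnase2a bait had a median of 12 genes and 47.5% GC, against 1 gene and 37.5% in the 25 least enriched. For B53 the medians were 1 gene and 40.1% GC at the top and 12 genes and 45.7% at the bottom. Single libraries differed: rho with GC was above 0 in all libraries of B26 (0.0433 to 0.643, the lowest 2 labelled G0), B87 (0.142 to 0.664) and B118 (0.113 to 0.539). It ran from -0.405 to 0.0684 at B53 (above 0 in 3 of 11, among them both labelled G0), from -0.167 to 0.129 at B7 and from -0.0143 to 0.121 at B44. The Spearman coefficient with the number of genes was below 0 in 11 of 11 libraries of B53 and 9 of 11 of B7, and above 0 in 9 of 10 of B118. These relations are across bins of 1 chromosome, which are not independent replicates.

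The bins named next were picked after their values were seen, from the 3 highest and 3 lowest of each profile, and not all follow this division. The Dnase2a bait was most enriched at 108000001 to 108500000, a bin of 27 genes with Ctcf, which encodes an architectural DNA-binding protein (log2 observed over expected 0.96 ± 0.94, SD, n = 10 libraries, above 0 in 9). It was also enriched at 123000001 to 123500000, with Irf8 and Cox4i1 (0.88 ± 0.69, above 0 in 10 of 10). The Whsc1l1 bait was enriched at 72500001 to 73000000, a bin of 23 genes, among them Upf1 and Crtc1 (0.79 ± 0.48). B7 was highest beside the bait near Maf, at 118500001 to 119000000, a bin of 0 genes and 43.8% GC (0.39 ± 0.54, above 0 in 8 of 11). In the 1-Mb window around that bait, B7 gave only 0.11 ± 0.67, above 0 in 5 of 11. Read from the bait near Maf, the window around B7 gave -0.31 ± 0.40, above 0 in 3 of 10. B53 was highest within Csmd1 at 17000001 to 17500000 (0.53 ± 0.59, above 0 in 9 of 11), and B7 had a high bin in Csmd1 at 16000001 to 16500000 (0.32 ± 0.22, above 0 in 10 of 11). B53 also met the bin of Cntnap4 at 115000001 to 115500000 (0.45 ± 0.40). The highest bin of the bait near Maf was 64000001 to 64500000, with Palld and Ddx60, of only 41.3% GC and 2 genes (0.67 ± 0.52, above 0 in 10 of 10), and that of B44 was 129500001 to 130000000, with Pard3 (0.58 ± 0.61, above 0 in 9 of 11). Among the 3 lowest of all 6 baits, and below 0 in every library, were 2 bins on either side of a stretch with 9 HindIII sites or fewer per bin (20000001 to 22000000). They are 19500001 to 20000000, with 3 genes (-1.46 at B7 to -2.61 at the Whsc1l1 bait), and 22000001 to 22500000, with 18 genes of the alpha-defensin cluster (-1.56 at the Dnase2a bait to -3.35 at the Whsc1l1 bait). These 2 bins themselves held 157 and 125 HindIII sites. Why they were low was not tested, so their values are not read as a property of the genes.

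**Figure D2:**
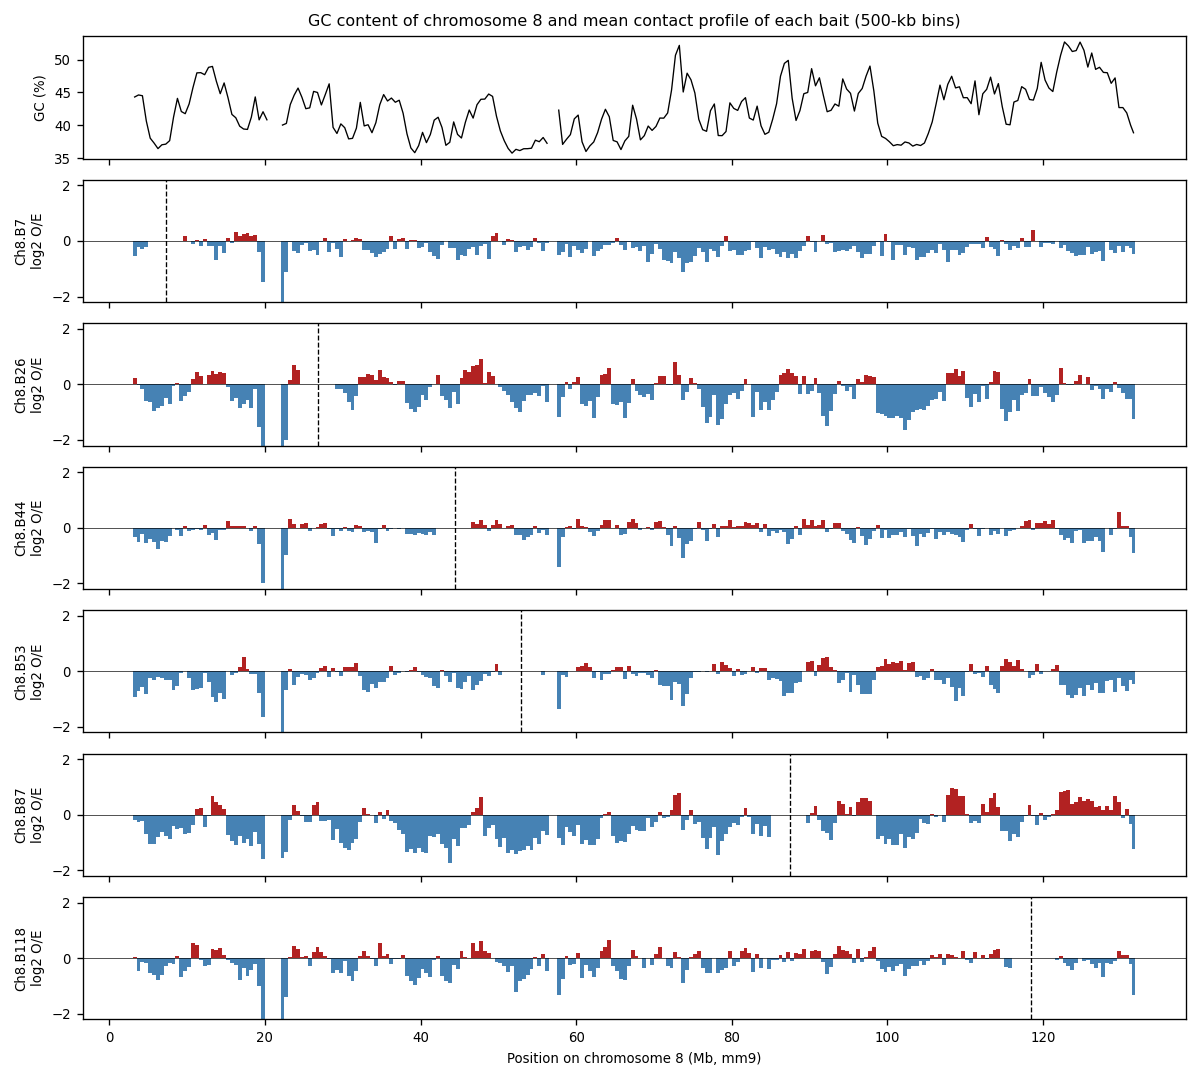
The top panel plots the GC percentage of 500-kb bins along chromosome 8 and the panels under it the mean log2 observed over expected captured sites of each bait over its 10 or 11 libraries (2 h technical replicates joined), with a dashed line at the bait. The profile of B87 rises where GC content is high (rho 0.795) and that of B53 where it is low (rho -0.399).

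The Whsc1l1 and Dnase2a baits, 60.7 Mb apart, were enriched from both ends, at 0.60 ± 0.50 (SD, n = 11) read from Whsc1l1 and 0.54 ± 0.51 (n = 10) read from Dnase2a, above 0 in 10 of 11 and 9 of 10 libraries. The other pairs of GC-rich baits were weaker. Whsc1l1 and the bait near Maf gave 0.14 ± 0.66 and 0.35 ± 0.62, above 0 in 6 of 11 and 6 of 10 libraries. Dnase2a and the bait near Maf gave 0.21 ± 0.26 and 0.06 ± 0.21, above 0 in 8 and 5 of 10. B53 and the Dnase2a bait, 34.5 Mb apart, were depleted on average, at -0.69 ± 0.96 (above 0 in 3 of 11) and -1.38 ± 0.98 (0 of 10). B44 and the Dnase2a bait gave -0.40 ± 0.38 and -1.31 ± 0.51. The 2 GC-poor baits B7 and B53 were not enriched for each other (-0.04 ± 0.38 and -0.26 ± 0.48, above 0 in 6 and 3 of 11 libraries), nor were B44 and B53 (-0.33 ± 0.22 and -0.28 ± 0.31). Over the 15 pairs the values from the 2 ends gave Pearson r 0.565 (permutation p = 0.0286, adjusted 0.0857 over 6 relations) and Spearman rho 0.411 (p = 0.131, adjusted 0.197). Neither coefficient passed the correction, and Pearson r was 0.467 without the 2 pairs farthest from the median. Mean profiles of the Whsc1l1 bait and the bait near Maf correlated at r 0.775 over 234 bins, those of Whsc1l1 and Dnase2a at 0.697, and those of B53 and Dnase2a at -0.379. Mean profiles across the GC division were not always opposite, with r 0.651 for B44 and the bait near Maf, 0.430 for B44 and Whsc1l1, and 0.241 and 0.125 for B7 with these 2 baits. Between single libraries of first hour or 2 to 4 h, the mean r of these 4 pairs was -0.0774 to 0.0596. Single libraries were thinned to 682 captured sites at every bait, while mean profiles averaged 10 or 11 libraries. Sparse sites lower r by themselves, so the lower values are not read as weaker contacts. The 3 pairs named before them also had r nearer to 0 between single libraries. In first hour and 2 to 4 h, mean r was 0.124 and 0.244 for the Whsc1l1 bait and the bait near Maf. It was 0.196 and 0.380 for Whsc1l1 and Dnase2a, and -0.103 and -0.199 for B53 and Dnase2a.

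Contacts within 2 Mb took on average a larger part of same-chromosome reads in libraries labelled 2 to 4 h than in those labelled 30 min and 1 h, at each of the 6 baits, but single labels did not follow in order. The comparison asks whether contacts differ before and after the interval in which the timing program is set. The difference was 14.6 ± 2.93 percentage points (SD, n = 6 baits, exact sign-flip permutation test, two-sided p = 0.0312, the smallest that 6 baits can give). It was 20.2 points at B44 (19.1 without 1 far site, named below, that held much of its far reads in some libraries) and 12.3 points at B7, and 8.61 points over the baits without the library labelled 4 h. By label the mean share over baits was 54.1% for 30 min, 33.8% for 1 h, 45.0% for 2 h, 60.7% for 3 h and 70.4% for 4 h, so that 30 min lay above 2 h. At the bait near Maf the mean of 30 min (67.4%) was above that of 2 to 4 h (65.4%). The libraries labelled 3 h and 4 h also had the fewest captured sites beyond 2 Mb, with medians over baits of 2031 and 1463. The median was 15860.5 in 1 h replicate 1. The difference in near share cannot be told apart from this difference in captured sites. The share of all reads on chromosome 8 moved the other way, with -4.93 ± 1.90 points (n = 6, exact p = 0.0312) and the largest difference at the Dnase2a bait, from 55.9% to 47.4%. This second call rested on single labelled libraries: without 1 h replicate 1 it was -0.0229 points, without 1 h replicate 2 it was -2.39, without 4 h it was -0.302, and without 30 min replicate 2 it was -13.97. On captured fragments it was -3.60 points (exact p = 0.0625), and without the far site of B44 it was -4.23 (exact p = 0.0625), with 0.745 at B44. The library labelled 30 min replicate 2 had 27.9% to 41.2% of reads on chromosome 8, against 58.7% to 74.8% in replicate 1. The baits were probably read from the same cultures, so the test asks whether baits move alike.

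**Figure D3:**
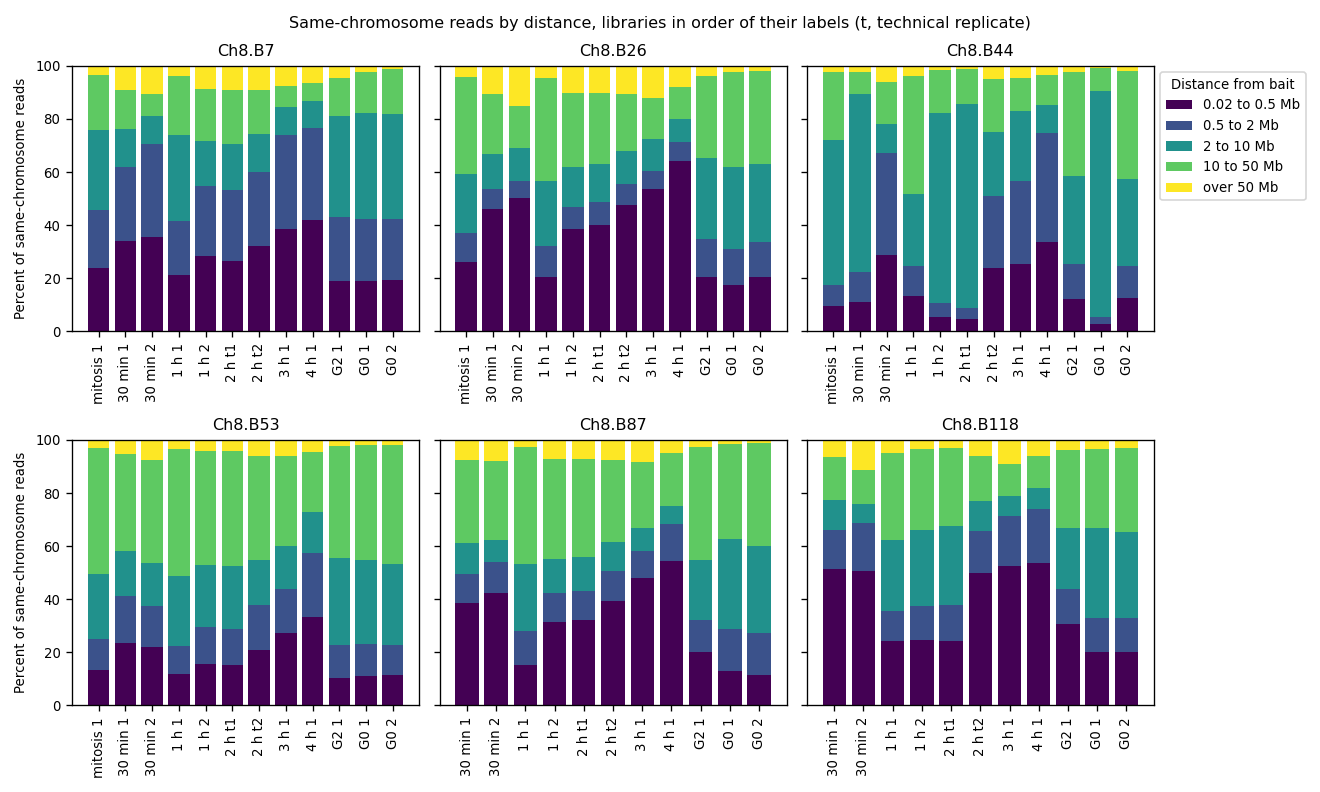
Each bar is 1 library of a chromosome 8 bait, in the order of the labelled times, and its colours give the percent of same-chromosome reads beyond 20 kb in 5 ranges of distance from the bait. Reads 2 to 10 Mb away make up 29.4% to 84.9% in the libraries labelled G0 and 6.70% to 15.3% in those labelled 4 h. The 84.9% is that of B44 in replicate 1, where 1 site holds 82.4% of reads beyond 2 Mb; the other G0 libraries have at most 40.2%.

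No 500-kb region of B7, B26, B44, B53, B87 or B118 passed the test between libraries labelled 2 to 4 h and those labelled first hour (30 min and 1 h). Of 1461 bins over 6 baits, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test and 0 in DESeq2. Under an unadjusted 0.05 there were 28 and 54, and on captured fragments edgeR had 1 of 1447. These counts lie below the share of 0.05 that chance alone gives. The tests thus appeared conservative for this comparison, and a count of 0 does not show that the labelled stages are alike. Within 2 Mb, 0 of 228 bins of 100 kb passed with either tool (10 and 16 unadjusted). Without the library labelled 2 h, edgeR called 30 long-range bins and 1 near-bait bin. In counts simulated with 1 common spread per bait, 36.4% of 4-fold and 91.1% of 16-fold changes were called among 1462 bins, so changes of 4-fold were mostly not detectable. The simulation had no differences in spread between bins and no reads piled on few captured sites. Its percentages need not hold for the real counts, least of all for the sparse libraries labelled 3 h and 4 h. The coefficient of variation between libraries of a stage was 0.512 at B44 to 0.880 at the Dnase2a bait.

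Long-range profiles of 1 labelled stage did not resemble each other more than profiles of the other stage. The difference in mean r, within minus between stages, was -0.0273 ± 0.0126 (n = 6 baits, exact permutation p = 0.0312), below 0 at all 6 baits. At the Whsc1l1 bait the means were 0.391 within and 0.416 between. This call was lost with all captured sites (-0.0111) and on read counts (-0.0141), and its sign turned without the library labelled 30 min replicate 2 (0.0184). Without the library labelled 3 h it was -0.0347 (exact p = 0.0625). Similarity to the library labelled 3 h was 0.0338 ± 0.0632 higher in r for the libraries labelled 2 h and 4 h than for those labelled first hour (n = 6, exact permutation p = 0.250). By label, mean r with that library was 0.485 for 4 h, 0.471 for 30 min, 0.266 for 2 h, 0.212 for 1 h, 0.169 for mitosis, 0.151 for G2 and 0.122 for G0. Without the library labelled 4 h the difference was -0.0757 (exact p = 0.0312). Without the library labelled 2 h it was 0.143.

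No difference was detected in contacts among the 6 baits, as a set, between these labelled stages, at -0.10 ± 0.41 on the log2 scale (15 pairs, permutation p = 0.384, 6 above 0 and 9 below). On read counts the difference was -0.471 (permutation p = 0.0943) and in 2-Mb windows -0.164 (permutation p = 0.0568). B53 with the Dnase2a bait had the lowest difference, -1.01, and the Whsc1l1 bait with the bait near Maf the highest, 0.54. Between the ends, r was 0.445 in libraries labelled first hour (permutation p = 0.0967, adjusted 0.193) and 0.569 in those labelled 2 to 4 h (p = 0.0267, adjusted 0.0857). The size of the correlation between profiles of different baits was 0.0463 ± 0.0562 higher in libraries labelled 2 to 4 h (15 pairs, permutation p = 0.00146, 12 pairs above 0). The 15 pairs share 6 baits, so they are not independent as the test takes them to be, and 6 baits as units allow no p under 0.0312. The Whsc1l1 and Dnase2a baits had the largest difference, from 0.196 to 0.380. With all captured sites in place of equal numbers this difference turned to -0.0955 (12 of 15 pairs below 0), and without the library labelled 3 h it was 0.00366. The relation of profiles to HindIII site density, a property of AT-rich sequence, differed by -0.00695 ± 0.0597 in rho (6 baits, exact permutation p = 0.719).

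Libraries labelled G0 had few reads near the bait and many at 2 to 50 Mb. Their share within 2 Mb was 28.9% ± 9.34 (SD over 6 baits), against 33.6% ± 8.71 for G2 and 31.4% ± 12.6 for mitosis (4 baits). The library labelled 1 h replicate 1 was as low, with a median over baits of 30.1%. The medians of G0 replicates 1 and 2 were 30.0% and 30.2%. The difference of G0 from libraries labelled 2 to 4 h was -29.6 ± 4.81 points, below 0 at 6 of 6 baits (exact permutation p = 0.0312). It was -36.5 points at B44 and -22.1 at B53. At B44 in replicate 1, 1 far site held 82.4% of reads beyond 2 Mb and the share near the bait was 5.48%, against 24.5% in replicate 2; without that site the B44 difference was -38.9 points. On captured fragments the difference over baits was -12.4 points. The share of reads on chromosome 8 was 23.0 ± 10.4 points higher (6 of 6 baits, exact p = 0.0312), with 33.3 points at the Whsc1l1 bait and 3.18 at the bait near Maf. Restricted to replicate 1, this share differed by 15.7 points (exact p = 0.0938), and without the library labelled 4 h by 18.4 points (exact p = 0.0625).

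Near the baits, 22 of 228 bins differed between libraries labelled G0 and 2 to 4 h in edgeR's quasi-likelihood test, 18 lower and 4 higher in G0. The balance of lower and higher bins depended on scaling: with read totals in place of TMM factors 17 passed, 8 lower and 9 higher, 12 of them among the 22. All 22 bins kept their sign with read totals. TMM factors of G0 lay above those of 2 to 4 h by 1.24 on the log2 scale at the Whsc1l1 bait and by 0.882 at the Dnase2a bait, which lowers the fold changes there by as much. Of the 22 bins, 21 had no overlap between the 2 libraries of one label and the 3 of the other. The Dnase2a and Whsc1l1 baits had 8 of the 22 bins each, B7 had 5, B44 had 1, and the other 2 baits had 0. At the Dnase2a bait the adjacent bin with Junb, an AP-1 transcription factor gene, and Prdx2, a peroxidase gene (87484073 to 87584072), was lower in libraries labelled G0 (log2 fold change -2.80 ± 0.57, SE, adjusted p = 0.000642; -1.92 with read totals). At the Whsc1l1 bait a gene-free bin 0.4 Mb away (26324323 to 26424322) was lower (-3.62 ± 0.79, adjusted p = 0.00503; -2.37 with read totals) and another 0.9 Mb away (27624323 to 27724322) was higher (1.61 ± 0.50, adjusted p = 0.0370; 2.82 with read totals). B7 had a lower bin at 6573961 to 6673960 (-0.81 ± 0.23, adjusted p = 0.0349) and a higher one at 5573961 to 5673960 (1.27 ± 0.34, adjusted p = 0.0309). B44 had a lower bin at 44967345 to 45067344 (-0.80 ± 0.22, adjusted p = 0.0206). Without either library labelled G0, 0 bins passed; without the library labelled 3 h, 4 h or 2 h, 3, 4 and 43 passed; and on captured fragments 0 passed. The 43 were 22 higher and 21 lower in G0.

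Beyond 2 Mb, 0 of 1461 bins differed between libraries labelled G0 and 2 to 4 h in edgeR, with 457 at an unadjusted p under 0.05, while DESeq2 called 361 (132 higher and 229 lower). Without the library labelled 2 h, edgeR called 233, and with read totals in place of TMM factors 60 (7 higher and 53 lower). G2 and mitosis had 1 library per bait, assumed to vary like the other stages, so any bin called for G2 describes that 1 library. Between the library labelled G2 and those labelled 2 to 4 h, 3 bins passed, all lower in G2 and all at B53, while on captured fragments 157 passed, 122 higher and 35 lower. Without the library labelled 2 h and the second 1 h library 4 passed, 3 higher and 1 lower, with 1 of the 3 among them. The bin at 9000001 to 9500000 with Fam155a had 17.95 CPM of tested bins, against 4810 ± 1004 (SD, n = 3; log2 fold change -7.73 ± 1.23, SE, adjusted p = 0.0304). The gene-free bin at 6500001 to 7000000 had 15.3, against 3267 ± 545 (-7.39 ± 1.22, adjusted p = 0.0304), and the bin with Shcbp1 at 4500001 to 5000000 had 0 reads against 2570 ± 377 CPM (adjusted p = 0.00468). With a replicate block only the last of the 3 passed (adjusted p = 0.0125, the others 0.0699). DESeq2 called 79 bins for G2.

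The remaining long-range comparisons called no region in edgeR. With 1 library labelled mitosis per bait, a count of 0 there does not show likeness to first hour. Between libraries labelled 1 h and 30 min, 0 of 1461 bins passed (223 unadjusted), and DESeq2 called 29. B44 and the bait near Maf held 84 and 67 of the unadjusted 223. Between mitosis and first hour, 0 of 975 bins at 4 baits passed, with 0 unadjusted in edgeR and, in DESeq2, 0 and 21. At B44 a single far site, at 42394901 on chromosome 8 and 2.02 Mb from the bait, took 0.0491% to 82.4% of reads beyond 2 Mb and over 5% in 8 of its 12 libraries.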

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

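The tests in this part were chosen after the results were seen, except the share of reads at shared sites. Among the 39 columns used in no comparison, 35 had their reads at another bait than the label names. A median of 11.5% of their reads lay within 100 kb of the bait found and at most 0.250% within 100 kb of the labelled one, which argues against a mixture of 2 baits in a library. The number of columns per bait equalled the number of labels per bait for 9 of 9 baits. Cut where a bait comes again, the columns fell into 7 sets, and all 7 equalled the sets of baits that the labels give per time and replicate, so the titles may stand in another order than the columns. No biological explanation was tested.

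The libraries labelled 1 h replicate 2 and 2 h technical replicate 1 shared captured sites at all 6 baits. Reads carried over in 1 direction only are argued against, since at least 91.3% of each library's reads on other chromosomes lay at the shared sites. An exchange of reads in both directions would also put most reads of both libraries at shared sites, so the share cannot exclude it. Like contacts at 1 h and 2 h are argued against too, since the overlap was at least 2.36 times that of 1 h replicate 2 with the other 2 h technical library. At B26, B44, B53 and B118 a library labelled G0 shared sites with both of these libraries as well, as given in the last paragraph. A technical pair alone leaves that unexplained, and the G0 library was not tested for carried-over reads. These G0 columns stood at place 2 at B26, B44 and B53, and at place 1 at B118. In the cell cycle order given next, each would be called 30 min replicate 1, and its sharing would still be unexplained. Sorted by the cell cycle (mitosis, 30 min, 1 h, 2 h, 3 h, 4 h, G2, G0), the labels would put the 2 h technical pair where the sharing pair stands at 6 of 6 baits, places 6 and 7 of 12 columns or 5 and 6 of 11. That is consistent with titles sorted by name over columns in cell cycle order, and stays a hypothesis; no library was given another label.

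In libraries labelled G0 the share within 2 Mb was 29.6 points below that of 2 to 4 h. Counted once per captured site the difference was -12.4 points, below 0 at 6 of 6 baits. These shares were not thinned to equal numbers of sites. Libraries labelled G0 captured 5954 to 17003 sites beyond 2 Mb, against 687 to 3150 in those labelled 3 h and 4 h. More far sites lower this share by themselves, so it cannot decide whether a few fragments with many reads are the cause. The library labelled G0 replicate 1 differed between baits, with the lowest of B7, B26, B44 and B53 lying 23.1 points of same-chromosome share above the higher of B87 and B118, which lack a library labelled mitosis. Paired by cell cycle order instead of label, the 22 libraries of B87 and B118 lay 6.48 points of same-chromosome share from the mean of the other 4 baits, against 11.1 points by label, a ratio of 0.583. Only the columns labelled G2 and G0 change partner between these pairings, so the ratio rests on them and not on all 22. Any order that puts the column missing at B87 and B118 first gives the same ratio. A shift of titles in the G2 and G0 columns may therefore account for the difference between baits in that share. The ratio cannot test the rest of the cell cycle order. The share within 2 Mb was not tested in this way. At all 6 baits it was highest in the last column, labelled 4 h (76.6% at B7, 68.4% at B87). Cell cycle order would call that column G0, so the low share in G0 would become a high one. An effect of serum starvation cannot be told apart from a shift of titles, because the labels themselves are in doubt.

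The library labelled 30 min replicate 2 stood apart from the other 3 first-hour libraries in same-chromosome share at B44 (39.5%, others 70.7% to 77.0%) and at B53 (31.5%, others 74.8% to 80.8%). Chance flags about 1 in 20 groups, and 2 of 12 were flagged, but this library was the lowest of the 4 at all 6 baits (27.9% to 41.2%, against 58.7% to 82.6% in the other 3), which the flag by group does not count.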

How the results depend on the processing

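Alternatives without 2 h and the second 1 h library, without B87 and B118, without the far B44 site, with read totals in place of TMM factors, and with GC or gene number in place of site density were chosen after seeing the data. Fits with 1.5 h joined to another stage were not run, because no 1.5 h column carried its labelled bait. Of 197 alternatives, 148 kept their direction and side of the threshold, or a count within 1.5 times, and 49 did not (24 moved, 11 reversed, 14 weaker); the cause was not tested. Long-range counts were 29 (1 h versus 30 min), 361 (G0) and 79 (G2) in DESeq2; 221 (G0) and 157 (G2, 122 higher) on captured fragments; 165 (G0) in 1-Mb bins; and 60 (G0, 7 higher, 53 lower) with read totals. The 3 G2 bins in 1-Mb bins were 1 higher and 2 lower. Near-bait G0 counts were 44 in DESeq2, 0 on captured fragments and 17 (9 higher, 8 lower) with read totals. Without 2 h and the second 1 h library, counts were 2 long-range and 1 near-bait for 2 to 4 h versus first hour, 120 and 34 (16 higher, 18 lower) for G0, and 4 long-range (3 higher, 1 lower) for G2. Without B87 and B118, G0 gave 43 long-range and 14 near-bait bins, and its same-chromosome and near differences were 28.1 and -28.9 points, where 4 baits allow no p under 0.125.

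The replicate block gave 1 G2 bin in place of 3 and changed no other bin count by over 1.5 times. Replicate numbers did not pair libraries: differences between replicates 1 and 2 correlated between labels at -0.530 to 0.462 over baits. On replicate 1 libraries (block), same-chromosome differences were -14.7 (2 to 4 h minus first hour) and 15.7 (G0, exact p = 0.0938), and near differences 18.6 and -31.2.

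Leaving out each replicate gave 0 to 30 long-range bins and 0 to 1 near-bait bins for 2 to 4 h versus first hour (the highest without 2 h), and 0 to 233 and 0 to 43 for G0. Same-chromosome differences ran from -13.97 to -0.0229 points (2 to 4 h) and 15.7 to 30.3 (G0), and near differences from 8.61 to 21.6 and -36.7 to -23.7. Profile similarity within minus between ran from -0.0536 to 0.0184, similarity to 3 h from -0.0757 to 0.143, site-density relation from -0.0185 to 0.00548, bait-to-bait contacts from -0.19 to -0.041, and between-bait similarity from 0.00366 to 0.112.

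The same-chromosome difference (2 to 4 h) was -3.60 points on captured fragments and -4.23 without the far B44 site (exact permutation p = 0.0625 for both). With all captured sites, within minus between was -0.0111, similarity to 3 h -0.0304, site density 0.0167 and between-bait similarity -0.0955; on read counts the first was -0.0141, site density 0.0254 and between-bait similarity -0.0251. In place of site density, GC gave 0.0418 and gene number 0.0394. Depth limits the libraries labelled 3 h and 4 h most, with as few as 687 captured sites beyond 2 Mb.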

Other observations

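The sign and size of a profile's relation to GC content differed between baits. The test was chosen after the profiles were seen and run on the same 6 profiles, so it describes them and cannot support a rule. The rho of the mean profile with GC rose with the GC percentage of the bait's own bin, from B53 (36.2%, rho -0.399) to the Dnase2a bait (49.9%, rho 0.795), with Pearson r 0.968 over 6 baits, and 0.980 without the 2 baits farthest from the median. That baits meet bins of like GC content stays open: the top and bottom 25 bins of B7 (37.1% GC) had medians of 41.8% and 41.9%, and those of B44 (40.5%) 43.2% and 42.2%. The means joined the 2 libraries labelled 2 h by that label, rho of single libraries had both signs at B7, B44 and B53, and the baits are 6 loci of 1 chromosome.

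The 7 G1 libraries of a bait, with the 2 h pair as 1, can be split into 3 and 4 in 35 ways. The labelled split gave 0 long-range and 0 near-bait bins, so that all 35 splits gave as many by construction and the test says nothing about chance; the highest others gave 117 and 47. The highest split set apart the libraries labelled 30 min replicate 2, 3 h and 4 h in both cases, and the next highest, with 96 and 30 bins, those labelled 1 h replicates 1 and 2 and 2 h. In all, 2 of 35 splits had any long-range bin and 5 of 35 any near-bait bin, so the larger differences among these libraries do not follow the labelled split. The labelled split parts 1 h replicate 2 from 2 h, 1 of whose technical libraries shares its sites. Both of the highest splits keep the 2 together, which bears on the ranking. So does depth: 30 min replicate 2, 3 h and 4 h had the fewest captured sites beyond 2 Mb among these libraries. Their medians over baits were 3364.5, 2031 and 1463, against 12009.5 to 15860.5 in the others. The highest split thus also parts sparse libraries from fuller ones, and the 2 cannot be told apart.

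At B118 the library labelled G0 replicate 2 shared sites with those labelled 1 h replicate 2 and 2 h technical replicate 1 at 15.1 and 14.7 times chance. At B53 the library labelled G0 replicate 1 did so, at 11.4 and 11.7 times, at B26 the same label at 5.87 and 5.66 times, and at B44 at 4.01 and 4.03 times (61.3% and 61.6% of the smaller library). At B7 the libraries labelled 30 min replicate 2 and 3 h shared 32.0% (14.6 times).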
